A study of Mus musculus with 12 samples.

How the data were processed

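RNA was measured in whole spinal cord of 12 mice aged 1 week, 1 library per mouse, on a background of B6J;CAST, which mixes C57BL/6J with CAST, a wild-derived strain. The labels place the libraries in 4 groups of 3: female wt, female P278KY, male wt and male P278KY. P278KY is an allele of Gars, the gene of glycyl-tRNA synthetase, carried over a wt allele. Libraries are named here by labelled sex, genotype and the mouse number of the labels, and no mouse number occurs in more than 1 group, so nothing pairs the groups.

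Per the labels' protocols, poly(A) RNA was fragmented, libraries were made with KAPA stranded mRNA kits, and sequencing was paired-end on an Illumina NextSeq instrument. Both of the kits that the protocol names are given for every library, so a kit cannot be assigned to a library. Bowtie2 2.2.0 and RSEM 1.2.12 are named in the submitters' processing notes, with no role stated there. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here. Per the file headers, each deposited file holds an expected count, a TPM value and an FPKM value for 38924 genes. The deposited expected count is an estimated number of fragments per gene that need not be whole, which happens where fragments fit several genes or transcripts and are divided among them. Near-identical copies and overlapping genes can therefore exchange counts. The deposited TPM values were scaled by the authors to transcript length and to the library total. The deposited FPKM values were not used here. No row lacked a gene name.

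Expected counts summed to between 27713981 and 43219891 per library, and between 22001 and 23173 genes were detected in each. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr over the 4 groups, which left 17995, and scaled with TMM factors. The main test was edgeR 4.0.16 quasi-likelihood (robust fit) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The genotype effect was fitted over all 12 libraries with labelled sex as a further term, and the sex effect came from the same fit. Within-sex effects and the genotype by sex interaction came from a fit with 1 mean per group. The common biological coefficient of variation was 23.9%. Standard errors of edgeR log2 fold changes were taken as the fold change over the square root of its F statistic. CPM values are counts scaled to the TMM-adjusted library total, and log2 CPM used a prior count of 2.

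Before the data were examined, 29 gene lists were fixed, covering stress pathways, synthetases, and markers of cord cells and of neighbouring tissues. Of their gene symbols, 361 were found in the files and 3 were not. Lists were tested with camera from limma 3.58.1 on log2 CPM with sex as a term and the preset inter-gene correlation of 0.01, adjusted over the 29 lists. Mean and median log2 fold changes of these lists come from a linear fit on log2 CPM. Fold changes of single members and counts of members higher or lower come from edgeR. Camera with a correlation estimated per list, and fry, which asks whether a list's genes move on balance in 1 direction, stand beside it. Gars was compared between 6 and 6 libraries with an exact two-sided permutation test over 924 splits, whose smallest p is 0.00216. Genes within 20 Mb of Gars were compared with all others by Fisher's exact test. Positions come from GENCODE M21 on GRCm38, joined by Ensembl identifier for 37607 genes. They serve as approximate places, since the authors' build is unknown.

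Genes named in the text follow a rule fixed in advance: Gars, every gene past the threshold for genotype, and the 10 with the smallest p when under 5 pass. Within each sex and for the interaction the rule takes the 2 with the smallest p where none passes, and for sex the 6 smallest in each direction. For a described list it takes up to 4 members past the threshold, or the 2 with the smallest p. Predicted genes were passed over. Other names are marked as chosen after their values were seen.

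Alternatives fixed in advance were RLE factors, library totals, no filter and a strict filter (CPM above 1 in 6 libraries), DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1), 1 surrogate variable from sva 3.50.0, another threshold, omission of sex chromosome genes, of the sex term and of the linked region, a fold threshold, other windows around Gars, and each library left out in turn. Alternatives chosen after seeing the data were the joint omission of 2 wt libraries whose sex marks disagreed with their labels, Y-linked expression in place of labelled sex, a skeletal muscle score as a term, permutation of list means, a p threshold of 0.01 near Gars, and omission of Fgf21 from its list.

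The procedure was tested on counts simulated for the 17995 genes from the real means, spreads and library sizes, with 200 genes changed, 50 at each of 4 folds. The changed genes were drawn from those with a mean above 1 CPM, so the rates do not cover lower genes such as Fgf21. Libraries were drawn independently of each other, so structure shared between real libraries was absent, and the rates may be better than on the real data. For the genotype effect, edgeR recovered 12% of genes changed 1.25-fold, 80% at 1.5-fold, 88% at 2-fold and 100% at 4-fold, and 5.4% of its 148 calls were false. DESeq2 recovered 26%, 88%, 94% and 100%, with 20.6% of 194 calls false. In females edgeR recovered 4%, 36%, 72% and 94%, with 8.8% of calls false, and in males 2%, 38%, 68% and 92%, with 3.8% false. For the interaction it recovered 0%, 14%, 54% and 86%, with 6.1% false, and for sex 32%, 64%, 84% and 96%, with 5.5% false. A simulated 1.2-fold rise of the stress response list was called by camera, and none of the other lists counted was. The neuron injury list, which shares Atf3 with it, was left out of that count. Genes were simulated independently of each other, so this does not show how often camera calls lists of correlated genes. The median over genes of the squared difference between a pair of libraries, in units of its counting variance, was between 1.14 and 6.51, against 0.455 for counting noise alone, so no pair of libraries looked like 1 library deposited under 2 names. Counting intervals given below cover counting error only.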

Results

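Spinal cord RNA was profiled in 12 mice aged 1 week, before the onset of disease according to the labels, 6 of them heterozygous for the P278KY allele of Gars and 6 wt. Gars encodes glycyl-tRNA synthetase, the enzyme that charges tRNA with glycine, and dominant mutations of the human gene cause a form of Charcot-Marie-Tooth disease, an inherited neuropathy of motor and sensory axons. Each genotype held 3 mice labelled female and 3 labelled male. Expected counts summed to between 27713981 (male P278KY 5) and 43219891 (the library labelled male wt 19). Libraries of the same group correlated with a median r of 0.9683 across genes and libraries of different groups with a median r of 0.9664, so the groups differed little as a whole. Replicates are separate mice.

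Sex marks went against the label in 2 of the 12 libraries, both wt. Xist, the RNA that coats the inactive X chromosome, stood at 762 to 1110 CPM in the other 5 libraries labelled female and at 1.2 CPM or less in the other 5 labelled male. The library labelled female wt 14 had 0.533 CPM of Xist and 45.1 CPM of Ddx3y, a Y-linked RNA helicase gene, whereas the library labelled male wt 19 had 860 CPM of Xist and 0.0233 CPM of Ddx3y. Ddx3y was at 75.0 to 93.3 CPM in the other 5 libraries labelled male. Labels were kept as given, and these libraries are called sex-discordant below. Both carry the wt label, so the comparison of genotypes keeps its 6 and 6 libraries, while every comparison by sex below contains them. Labelled sex is also a term of the genotype fit and of the list tests, so their labels enter there too.

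**Figure D1:**
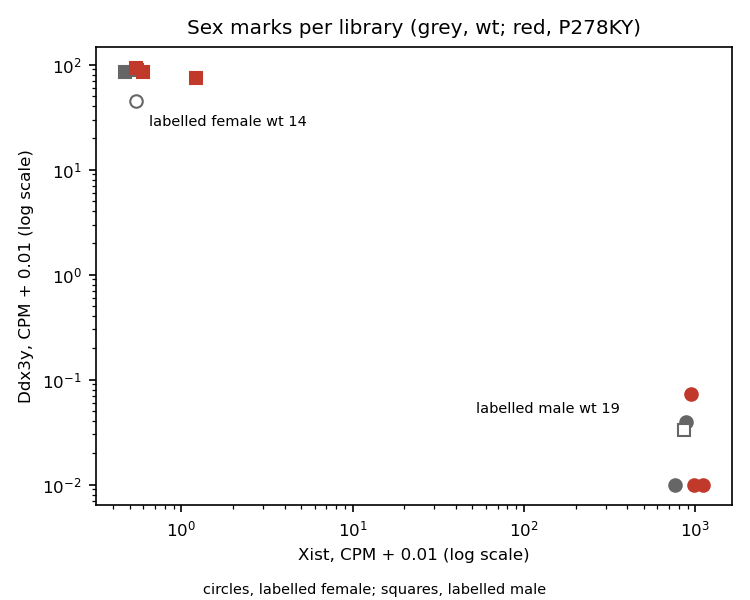
Xist (horizontal) against Ddx3y (vertical), each in CPM plus 0.01 on log scales, with 1 point per library, circles for libraries labelled female, squares for those labelled male, grey for wt and red for P278KY. The library labelled female wt 14 lies with the libraries labelled male at 0.533 CPM of Xist, and the library labelled male wt 19 lies with those labelled female at 860 CPM.

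Gars itself (ENSMUSG00000029777, chromosome 6, 55038007 to 55079500 on GRCm38, plus strand) was read first, since the mutation alters the protein and not necessarily its mRNA. Its level was 124 ± 6.74 CPM in wt and 131 ± 7.36 CPM in P278KY libraries (SD, n = 6 each; exact two-sided permutation p = 0.132). Per library it was 135, 123 and 130 CPM in female wt 1, 2 and the library labelled female wt 14, and 121, 117 and 120 CPM in male wt 6, 9 and the library labelled male wt 19. It was 128, 126 and 121 CPM in female P278KY 4, 7 and 10, and 137, 140 and 135 CPM in male P278KY 3, 5 and 13. The log2 fold change was 0.07 ± 0.05 (SE; edgeR adjusted p = 1), so with the sexes pooled no difference in Gars mRNA was called. Within sexes as labelled it was -0.05 ± 0.05 in females (edgeR adjusted p = 0.756) and 0.20 ± 0.05 in males (edgeR adjusted p = 0.891), where all 3 P278KY libraries lay above all 3 labelled wt. The interaction was -0.25 ± 0.07 (edgeR adjusted p = 0.225), and none of these passed the threshold.

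The comparison of P278KY with wt asked which transcripts the mutation alters before disease onset. Fgf21, a secreted stress hormone of the fibroblast growth factor family, rose in the P278KY cords and was the 1 gene of 17995 past the threshold. It was nearly absent from wt libraries, with 1 count in the library labelled female wt 14 and 0 in the other 5. All 6 P278KY libraries held it, with 15 to 48 counts each. The totals of 165 and 1 counts give a ratio of 188 (95% exact Poisson interval 33.3 to 7480), and the mean level was 0.904 ± 0.381 CPM against 0.00523 ± 0.0128 CPM (SD, n = 6 each). The fitted log2 fold change, which depends on the prior count, was 6.71 ± 0.60 (SE; edgeR adjusted p = 0.00137). Fgf21 (ENSMUSG00000030827) lies on chromosome 7 at 45613886 to 45615490 on the minus strand.

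The 10 genes with the next smallest p, predicted genes passed over, did not pass in edgeR, with adjusted p of 0.107 to 0.312, and are given as values. Several belong to amino acid metabolism or to the stress response: Cars, the cysteinyl-tRNA synthetase gene, with a log2 fold change of 0.37 ± 0.05 (SE); Mars, the methionyl-tRNA synthetase gene, with 0.22 ± 0.03; and Aldh18a1, an enzyme of proline synthesis, with 0.30 ± 0.05. Atf4, the transcription factor at the centre of the integrated stress response, had 0.36 ± 0.06, from 72.7 ± 6.24 CPM in wt to 93.3 ± 3.94 CPM in P278KY (SD, n = 6 each). Its targets Chac1 (0.52 ± 0.09), which degrades glutathione, Ddit3 (0.39 ± 0.07), which encodes CHOP, and the cationic amino acid transporter Slc7a3 (0.43 ± 0.08) had the same sign. Cass4, a scaffold protein gene, had 1.15 ± 0.22, from 0.540 to 1.2 CPM. Kcng4, a potassium channel subunit gene, had -0.72 ± 0.14, from 6.95 to 4.33 CPM. Each of these genes had all 6 P278KY libraries on 1 side of all 6 wt libraries. Cbx3, a heterochromatin protein gene 3.6 Mb from Gars, had 0.49 ± 0.08, with 5 of 6 P278KY libraries above every wt library. Mars and Ddit3 lie on opposite strands of chromosome 10 and share 68 bp at their ends, and Cass4 shares 7954 bp with the antisense gene Gm14455, so part of these counts may belong to the partner where strand was not used.

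**Figure D2:**
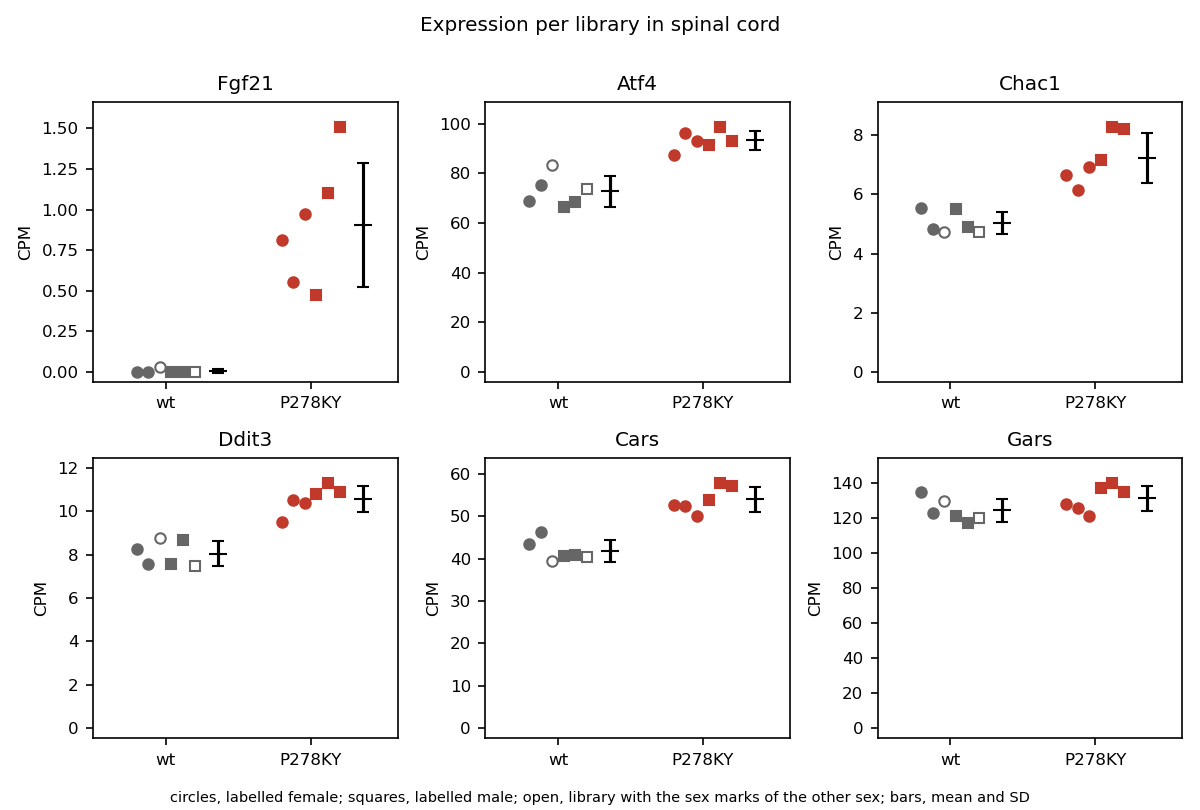
CPM (vertical) of Fgf21, Atf4, Chac1, Ddit3, Cars and Gars in each library by genotype, circles for libraries labelled female, squares for those labelled male, open marks for the libraries labelled female wt 14 and male wt 19, and bars for mean and SD of 6. Fgf21 lies between 0.473 and 1.51 CPM in P278KY libraries and at or below 0.0314 CPM in wt, while Gars overlaps between the genotypes.

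By genotype, 736 genes had an unadjusted p under 0.05 where 900 would be expected by chance, and 40 genes had all libraries of 1 genotype above all of the other, where chance gives 39.0. DESeq2 called 34 genes, 27 higher and 7 lower in P278KY, among them all 11 genes above and 6 members of the stress response list. Fgf21 had an edgeR adjusted p of 0.0537 without the library labelled female wt 14, after which all wt libraries are at 0, and of 0.0677 without that library and the library labelled male wt 19, while its log2 fold change was 7.94 and 7.84. In that first case Atf4 was the 1 call (edgeR adjusted p = 0.0435). There were 3 calls without female wt 2, Cbx3, Fgf21 and Cars, and 2 without female P278KY 10. A filter of CPM above 1 in 6 libraries removed Fgf21 from the test and left 0 calls. With Y-linked expression in place of labelled sex, chosen after seeing the data, Fgf21 passed (edgeR adjusted p = 0.00104).

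Of the 31 tested members of the integrated stress response list (targets of ATF4), fixed in advance, 30 had a higher level in P278KY as fitted by edgeR. On log2 CPM, where the prior count lowers the fold change of scarce genes such as Fgf21, the mean log2 fold change was 0.33 and the median 0.15. The list rose (camera adjusted p = 2.07e-18; adjusted p = 0.0307 with an estimated correlation; fry adjusted p = 0.00646), and it was the 1 list that held with an estimated correlation. Adjusted over the list alone, 8 members passed, all higher, against 1 when adjusted over all genes; Fgf21, Atf4, Chac1 and Ddit3 led them. The mean of the list was 3.86 ± 0.09 log2 CPM in wt and 4.19 ± 0.09 in P278KY (SD, n = 6 each; exact permutation p = 0.00216, the smallest this design can give, and 0.0628 adjusted over the 29 lists). Without Fgf21 the mean log2 fold change of the other 30 members was 0.21 (camera adjusted p = 1.68e-15; adjusted p = 0.0452 with an estimated correlation), with 4 of 6 P278KY libraries above every wt library (exact permutation p = 0.00649, two-sided). In these same P278KY libraries skeletal muscle markers were higher as well, as described below.

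Cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, were called higher as a group (20 tested, 14 with a higher fitted level; mean log2 fold change 0.09; camera adjusted p = 3.29e-09). The call was lost with an estimated correlation (camera adjusted p = 0.187) and kept with fry (adjusted p = 0.0336). Adjusted over the list alone, 7 members passed, all higher, against 0 adjusted over all genes. The leading members were Cars (1.29-fold), Mars (1.16-fold), Yars (1.13-fold) and Iars (1.13-fold). The list mean was 6.18 ± 0.04 log2 CPM in wt and 6.27 ± 0.03 in P278KY (SD, n = 6 each; exact permutation p = 0.00433, adjusted 0.0628). By contrast, the ATF6 and XBP1 targets of the unfolded protein response were not called (17 tested, 4 with a higher and 13 with a lower fitted level; camera adjusted p = 0.0545; 0 members past adjusted over the list alone), led by Manf at -0.12 ± 0.06 and Pdia4 at -0.10 ± 0.04 log2 (SE). Of the 15 genes of eIF2 kinases, eIF2 and eIF2B subunits and their regulators (Ppp1r15b, Impact and Gcn1), which act upstream of ATF4, Eif2s2 alone passed adjusted over the list alone (log2 fold change 0.16 ± 0.04). The list was not called (camera adjusted p = 0.99).

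**Figure D3:**
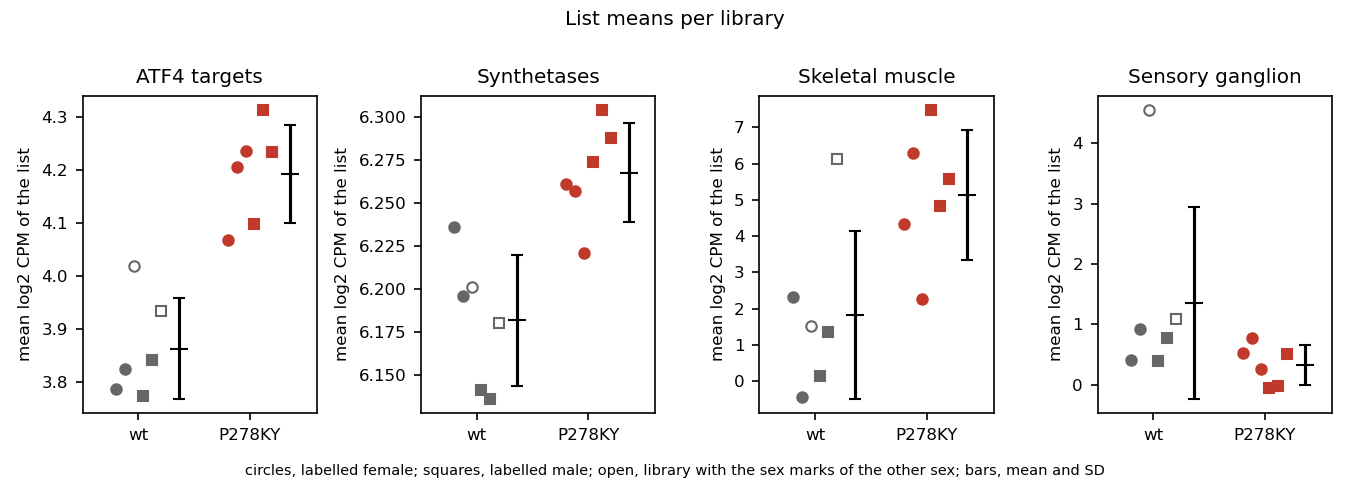
Mean log2 CPM (vertical, scales differ) of 4 fixed lists in each library by genotype, with symbols as labelled in the picture and bars for mean and SD of 6. The stress response list lies at 4.02 or lower in wt and at 4.07 or higher in P278KY, whereas the skeletal muscle list overlaps between genotypes, with the library labelled male wt 19 at 6.12.

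Markers of tissues next to the cord varied widely between libraries, and the calls by genotype described here held neither with an estimated correlation nor by permutation (adjusted p of 0.204 or more). All 10 skeletal muscle genes, such as embryonic myosin Myh3 (log2 fold change 2.43 ± 0.89) and alpha actin Acta1 (3.12 ± 1.33), had a higher fitted level in P278KY (camera adjusted p = 1.06e-13; adjusted p = 0.263 with an estimated correlation; 0 past adjusted over the list alone; exact permutation p = 0.0281, adjusted 0.204). Acta1 ranged from 2.68 to 289 CPM in wt, the highest being the library labelled male wt 19, and from 22.2 to 788 CPM in P278KY. Dorsal root ganglion neuron genes were called lower (9 of 9; camera adjusted p = 0.00085; adjusted p = 0.685 with an estimated correlation), with Scn10a, a sensory sodium channel gene, at 96.9 CPM in the library labelled female wt 14 and at most 2.43 CPM elsewhere. Most of this difference came with that library: without it the list mean differed by -0.39 log2 against -1.03 (exact permutation p = 0.0758 against 0.0368), and in libraries labelled female by -0.15 against -1.44, while camera still called the list (adjusted p = 0.00496). Schwann cell genes were called lower (10 of 10, led by Drp2 and Dhh; adjusted p = 0.0124; adjusted p = 0.84 with an estimated correlation). Genes of meninges and fibroblasts, led by Col1a2 and Lum (adjusted p = 0.0436; 0.84 with an estimated correlation), and of cartilage and bone, led by Ibsp and Sp7 (adjusted p = 0.0485; 0.83 with an estimated correlation), were called higher. Single libraries left out ended these last 3 calls: male P278KY 3 (camera adjusted p = 0.234) or male wt 6 (0.285) for Schwann cells, and several for the others, most so female wt 1 for meninges (0.441) and male P278KY 5 for cartilage (0.217). With the muscle score as a further term, chosen after seeing the data, these 3 calls were lost as well (camera adjusted p = 0.95, 0.564 and 0.579), while the dorsal root ganglion call stayed (0.00293). Acta1 and Scn10a were singled out after their values were seen.

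Among the cord's own cells, motor neuron genes were called lower (10 of 14 with a lower fitted level, led by Lhx4 at -0.28 ± 0.09 and Mnx1 at -0.30 ± 0.16 log2; camera adjusted p = 0.0207), a call lost with an estimated correlation (adjusted p = 0.685). This call was also lost in camera without the library labelled female wt 14 (adjusted p = 0.0741), which had the highest list mean (4.41 log2 CPM), and without male wt 9 (0.134), female P278KY 10 (0.0663) or male wt 6 (0.0517). With the muscle score as a further term, chosen after seeing the data, its direction turned (camera adjusted p = 0.987). Activated microglia genes were called higher, led by the lipase gene Lpl (0.77 ± 0.37) and Gpnmb (1.09 ± 0.57; adjusted p = 0.017; 0.763 with an estimated correlation), and so were mitochondrially encoded genes, led by mt-Atp8 and mt-Nd3 (adjusted p = 0.0436; 0.938 with an estimated correlation). The microglia call was lost without female P278KY 10 (camera adjusted p = 0.164) or male wt 6 (0.0871) and with the muscle score as a further term (0.574), and the mitochondrial call without any of several single libraries, most so male wt 6 (0.705). In each of these 3 lists 0 members passed adjusted over the list alone. The remaining cell type lists were not called: neurons (camera adjusted p = 0.0739, led by the neurofilament genes Nefh at -0.28 ± 0.10 and Nefm at -0.25 ± 0.09), excitatory and inhibitory transmission (0.719), astrocytes (0.99), oligodendrocyte precursors (0.719), myelinating oligodendrocytes (0.0545), microglia (0.132), endothelium (0.491), red blood cells (0.175), and bone marrow and neutrophils (0.99). Neither were reactive astrocytes (0.431), immediate early genes (0.99), interferon response (0.488), cholesterol synthesis (0.103), cell cycle (0.99), Y-linked genes (0.99), or partners reported for mutant glycyl-tRNA synthetase (0.99), nor the neuron injury list (0.151), whose mean of 0.29 against a median of 0.02 log2 came mostly from Csrp3, also a muscle gene, at 3.12 ± 0.97, and whose list mean had an exact permutation p of 0.00649 (adjusted 0.0628). In the lists of partners and of transmission the median was above 0 while the mean and the test were below 0, for astrocytes and for bone marrow both lay below 0 while the test pointed up, and for the eIF2 list the median alone was below 0.

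Because the labels give a mixed strain background, genes near Gars were compared with the rest. None of the 226 tested genes within 20 Mb passed the threshold for genotype. At an unadjusted p under 0.001 there was 1 gene near Gars, Cbx3, against 21 of 17496 elsewhere (odds ratio 3.70, 95% interval 0.089 to 23.2; Fisher's exact two-sided p = 0.246). The odds ratio became 8.60 (exact p = 0.0268) without female wt 1, 6.70 (exact p = 0.0409) without female wt 2 and 6.72 (exact p = 0.0408) without female P278KY 4, in each case with 2 genes near Gars, and it was 2.32 and 1.21 without the library labelled female wt 14 or male wt 19. With other regions it was 7.16 within 10 Mb (exact p = 0.137) and 1.92 for the whole chromosome (exact p = 0.299), and with DESeq2 2.41 (exact p = 0.137).

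**Figure D4:**
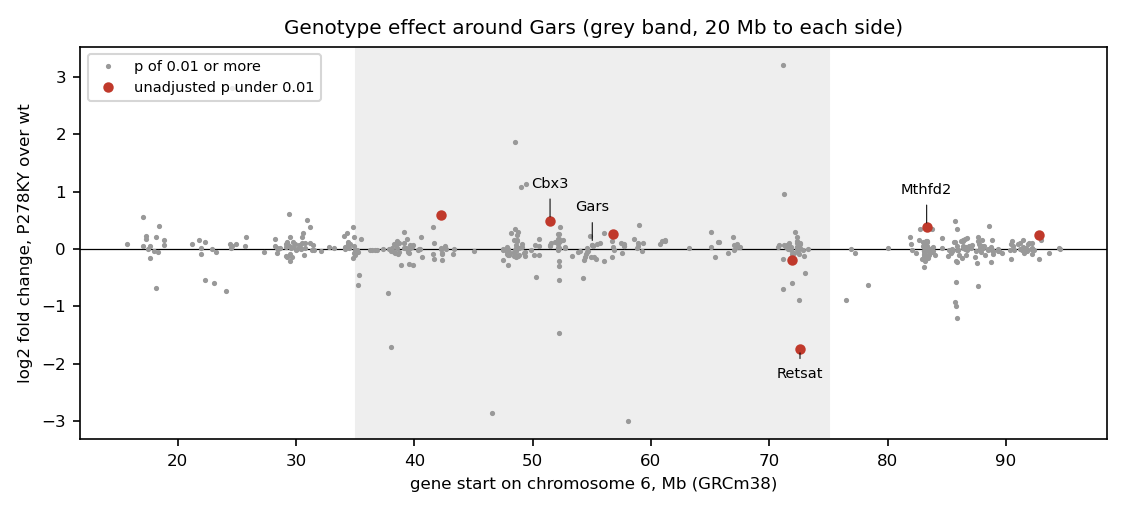
Log2 fold change of P278KY over wt (vertical) against gene start on chromosome 6 in Mb of GRCm38 (horizontal), 1 point per tested gene, the grey band marking 20 Mb to each side of Gars and red points an unadjusted p under 0.01. Cbx3 at 0.49 lies 3.6 Mb from Gars, and Retsat at -1.74 lies 17.6 Mb from it.

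Within females as labelled, Trove2, the gene of the RNA-binding protein Ro60, had a log2 fold change of 0.39 ± 0.06 (SE) and Kcng4 had -1.02 ± 0.16 (edgeR adjusted p = 0.161 for both). Neither passed, and no gene did: edgeR gave 0 calls with 1929 genes at an unadjusted p under 0.05, and DESeq2 gave 283. Without the library labelled female wt 14, edgeR gave 9 calls, and without female wt 2 it gave 2. With both sex-discordant libraries left out, there were 11 (7 higher and 4 lower), including Srp9 and Zfp783, named after their values were seen. Within males as labelled, Cars had 0.47 ± 0.06 and Fgf21 8.07 ± 0.98 (edgeR adjusted p = 0.144 for both), with 0 calls, 884 genes at an unadjusted p under 0.05 and 34 calls by DESeq2. There were 4 calls in males without the library labelled female wt 14, which enters through the shared spread, 2 without female P278KY 10, and 4 (1 higher and 3 lower) without both discordant libraries, including Retsat.

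Trove2 and Chchd10, a gene of a mitochondrial protein, led the interaction of genotype and sex. Trove2 had a log2 difference between the effects in females and males of 0.65 ± 0.08 and Chchd10 of -0.67 ± 0.09 (SE, edgeR adjusted p = 0.0702 for both), and neither passed. In both genes the sex-discordant libraries lay with the wt libraries of their label, against their sex marks. Both genes were picked for their small p in an interaction defined by the labels. Agreement with the labels was thus largely set by that choice and is no evidence that the labels are right. Trove2 was at 56.9 CPM in the library labelled female wt 14 (56.1 and 63.2 in female wt 1 and 2). It was at 82.1 CPM in that labelled male wt 19 (84.8 and 87.9 in male wt 6 and 9). Chchd10 was at 52.3 and 38.8 CPM in these 2 libraries. Grouped by sex marks, neither gene would separate the genotypes fully in either sex. EdgeR gave 0 calls with 1967 genes at an unadjusted p under 0.05, and DESeq2 gave 269. There were 3 calls without the library labelled female wt 14, 1 without female wt 2, and 5 without both discordant libraries. Stress response genes showed no difference between sexes that the design could resolve: the list mean was higher in P278KY by 0.29 log2 CPM in libraries labelled female and by 0.37 in those labelled male (exact permutation p of the difference = 0.77). Fgf21 had an interaction adjusted p of 0.657 in edgeR.

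Sex as labelled gave 0 calls in edgeR, with 827 genes at an unadjusted p under 0.05, and 30 in DESeq2. The smallest edgeR adjusted p over all genes was 0.203. With predicted genes passed over, the smallest p belonged to Disp1, Cd9, St6gal1, Eps8l1, Fmo1 and Ptpn13, with fitted levels higher in females by 0.39 to 0.82 log2. In the other direction they were Brox, Tfb2m, Rgs5, Pxmp2, Zmat3 and Pde6b, with log2 differences of -0.18 to -1.47 (edgeR adjusted p of 0.756 to 0.764 over these 12 genes). Xist had 4.91 ± 3.41 (SE) and Ddx3y -4.39 ± 2.15, neither past the threshold. Without both sex-discordant libraries, Xist at 10.45 ± 0.19 (edgeR adjusted p = 8.79e-10), the X-linked Kdm6a and Eif2s3x, and the Y-linked Ddx3y, Uty, Eif2s3y and Kdm5d were among 10 calls, 6 higher and 4 lower in females. Leaving out male wt 6 gave 25 calls, and leaving out female wt 1 or female P278KY 10 gave 1 each.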

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

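Tests of the stress response pattern and of the sex marks were chosen after the values were seen, and the counts over other splits of the libraries were set before their results were seen.

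Within each genotype, sets of 6 values were formed from the list means, Gars, and the genes named for genotype, over all libraries or within a sex. Genes named only for the interaction or for sex were left out. In all, 84 sets were examined for 1 library far from the others, and 9 had one, where chance gives about 1 in 20. Of these, Fgf21 in the library labelled female wt 14 (0.0314 CPM) rests on 1 count with the other wt libraries at 0, where any count is flagged, which leaves 8 of 83 sets against 4.15 by chance. That library also stood apart in Mars (53.4 CPM against 48.7 to 50.2), dorsal root ganglion genes (4.55 log2 CPM against 0.39 to 1.09), the reported partners of the mutant synthetase (6.44 against 5.74 to 5.88) and immediate early genes (2.57 against 2.07 to 2.26). Cbx3 stood apart in female wt 2 (169 CPM against 116 to 136) and in male P278KY 13 (169 CPM against 183 to 190). Schwann cell genes stood apart in male P278KY 3 (0.822 log2 CPM against 3.77 to 5.02), and bone marrow and neutrophil genes in female P278KY 4 (0.756 against 2.46 to 3.29). Trove2 moved in opposite directions in the sexes as labelled, every P278KY library above every wt library in females and below in males, with an interaction of 0.65 log2 that did not pass in edgeR (adjusted p = 0.0702). Chchd10, not among the sets examined, showed the same full separation with the directions reversed. For both genes this holds by label only and not by sex marks, as described above.

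Xist and Y-linked counts went against the labelled sex in 2 wt libraries. A sizeable mixture of RNA from both sexes is argued against by the absent marks: Xist was at 0.533 CPM in the library labelled female wt 14, inside the range of the other libraries labelled male (at most 1.2), and Ddx3y was at 0.0233 CPM in the library labelled male wt 19 (at most 0.0629 in the others labelled female). In that library Uty, Eif2s3y and Kdm5d were at 0.0467, 0.0467 and 0.0233 CPM, above all others labelled female. These levels are close to 0, and a trace of male RNA is not excluded. An exchange of the 2 sex labels within the wt group and mis-sexing of both pups cannot be told apart, since either puts 1 library out of place on each side, which is the pattern already seen (2 libraries). In the library labelled female wt 14 Ddx3y (45.1 CPM), Eif2s3y (41.7 CPM) and Uty (10.8 CPM) all lay below the other libraries labelled male, and this was not explained.

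Stress response genes were higher in P278KY libraries, where skeletal muscle RNA was higher too. Muscle RNA as the whole cause is argued against, while a part is not excluded. With the muscle score as a further term the genotype coefficient of the list mean without Fgf21 was 0.188 ± 0.078 log2 (SE), against 0.214 ± 0.054 without that term. The coefficient fell little. However, the score is an imperfect measure of muscle RNA and was itself higher in P278KY, so some coefficient could remain under this cause. Several libraries did not follow their muscle RNA. The library labelled male wt 19 had a muscle mean of 6.117 log2 CPM, a full stress list mean of 3.934 and 0 Fgf21 counts. Female P278KY 10 had 2.263, 4.235 and 31 counts. Male P278KY 3, highest in muscle at 7.478, had a stress list mean of 4.098. Fgf21 kept its call with the muscle term (edgeR log2 fold change 7.55, adjusted p = 0.0064). Alleles linked to Gars acting on list members of its chromosome are argued against as the whole cause. Only 2 members lie there, and the mean of the other 29, Fgf21 among them, differed by 0.336 log2 CPM, against 0.329 for all. Their exact permutation p of 0.00216 adds little, since the full list already separated the genotypes. The 2 sex-discordant libraries are argued against as its source: without them the list mean differed by 0.386 log2 CPM, against 0.329 with them. The exact permutation p without them was 0.00476, the smallest that 210 splits can give. That p was fixed beforehand, since all P278KY libraries already lay above all wt libraries, and carries no weight. A response to the mutation remains a hypothesis, and litter, cell composition and strain alleles, unlinked to Gars or linked to it and acting on genes elsewhere, stay open because they were not tested.

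Counts of calls were set against other splits of the same libraries, made within sex for genotype and within genotype for sex, and chance was excluded for none that the splits could test. For the genotype effect 20 of 100 splits gave at least the observed 1 call in edgeR, with up to 1596 in another split. With DESeq2, 10 of 30 gave at least the 34 calls, with up to 2679. Those 30 were the first of the 100 in a fixed order, not a random draw. That order begins with splits that keep the female libraries grouped as labelled, so the DESeq2 share does not measure chance. The 10 lists called by camera were matched or exceeded in 43 of 100 splits, with up to 21 lists, so the number of lists called carries no weight by itself. The interaction and the sex effect had 0 calls, a count that every split reaches by construction (100 of 100, with up to 1767 and 1498 calls), so the splits test nothing there. Within a sex only 10 splits exist, too few for a share under 0.05; the real count was 0 and the highest other count was 652 in females and 0 in males. Splits with so many calls, far above the real counts, point to some structure of the libraries, and no test here identified it.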

How the results depend on the processing

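Of 705 recomputed values, 614 under alternatives fixed in advance and 91 under alternatives chosen after seeing the data, 585 kept their direction and their side of the threshold, 69 kept the direction and lost the threshold, 18 newly passed, 32 counts or values moved, and 1 changed direction; causes were not tested unless stated. Fgf21 had an adjusted p under 0.05 in 24 of the 26 settings that gave one (0.0011 to 0.0537 over single libraries left out). The number of genotype calls was 34 with DESeq2, 2 without a sex term, 0 with the strict filter, which removes Fgf21 from the test, 0 without both sex-discordant libraries (chosen after seeing the data, as wherever named here) and 1 to 3 with single libraries left out. In females it was 283 with DESeq2, 11 without both discordant libraries and 0 to 9 over single libraries, and in males 34, 4 and 0 to 4. The interaction had 269 calls with DESeq2, 3 at an adjusted p under 0.10, 3 with no filter, 5 without both discordant libraries and 0 to 3 over single libraries. Sex had 30 with DESeq2, 10 without both discordant libraries, where the marks match the labels, and 0 to 25 over single libraries. The number of lists called was 1 with an estimated correlation, 2 with fry, 0 by permutation, 16 without both discordant libraries, 6 with the muscle score as a term (those last 3 chosen after seeing the data) and 5 to 13 over single libraries, with 5 without male wt 6 and 6 without female P278KY 10. The stress response list had an adjusted permutation p of 0.0628, and 8.8e-22 to 2.69e-13 in camera over single libraries. The synthetase list had 0.0628 by permutation, 0.187 with an estimated correlation, and 3.63e-11 to 3.07e-06 over single libraries. The motor neuron list turned from lower to higher with the muscle term (adjusted p = 0.987). Near Gars the odds ratio was 3.09 at an unadjusted p under 0.01 (Fisher's exact p = 0.0271), chosen after seeing the data, and 1.21 to 8.60 over single libraries. Gars kept its side of the threshold in every setting run. Fgf21 rests on 165 counts in P278KY and 1 in wt libraries, so depth limits the precision of its fold change.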

Other observations

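The genes in this part were chosen after their values were seen, and the test of the synthetases was chosen after their fold changes were seen.

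Some genes of slow-twitch and cardiac muscle outside the fixed lists, whose number was not tested against chance, were among the 34 DESeq2 calls for genotype: Myh7, a slow myosin heavy chain, had a log2 fold change of 3.74 ± 0.77 (SE; DESeq2 adjusted p = 0.00264), Tnnt1, a slow troponin, 3.57 ± 0.79 (DESeq2 adjusted p = 0.00895), and the myoglobin gene Mb 3.50 ± 0.64 (DESeq2 adjusted p = 0.000173). None passed in edgeR (adjusted p of 1, 1 and 0.643). Muscle RNA was uneven between these same libraries, with a skeletal muscle list mean of -0.424 to 6.117 log2 CPM in wt and 2.263 to 7.478 in P278KY. In simulation 20.6% of the DESeq2 calls were false, and 10 of 30 splits, not drawn at random, reached 34 calls. Mthfd2, a mitochondrial folate enzyme of the stress response list that lies 28.3 Mb from Gars, had 0.38 ± 0.09 and passed in DESeq2 (adjusted p = 0.0382) and adjusted over the list alone (0.00437), not over all genes in edgeR (0.714).

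Retsat, the retinol saturase gene on chromosome 6 (72598475 to 72608425 on GRCm38, plus strand, 17.6 Mb from Gars), took separate levels in wt libraries. It was at 8.40 and 8.97 CPM in female wt 1 and 2, at 38.4 and 39.6 CPM in male wt 6 and 9, and at 43.9 and 46.1 CPM in the libraries labelled female wt 14 and male wt 19. All 6 P278KY libraries lay between 7.78 and 10.3 CPM. The genotype effect was -1.74 ± 0.43 log2 (SE; edgeR adjusted p = 1, DESeq2 adjusted p = 0.033).

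Synthetase genes differed in how far they moved. A hypothesis is that the rise follows membership in the ATF4 program and is not shared by all synthetases. The 12 synthetases commonly listed as ATF4 targets, Gars among them, had a mean log2 fold change of 0.14 ± 0.09 (SD over genes) with 12 of 12 above 0, and the other 8 had 0.01 ± 0.03 with 2 of 8 above 0. The difference of 0.13 (exact two-sided permutation p over genes = 0.00054) does not decide on the hypothesis: the 2 sets were drawn up from general knowledge after the leading synthetases had been seen, and the genes are not independent (estimated correlation 0.206 within the list). Fresh libraries would be needed to test it.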
